A study of Homo sapiens with 9 samples.

How the data were processed

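RNA of 9 libraries was measured with Ion AmpliSeq, a whole-transcriptome panel of targeted multiplex PCR that amplifies a short stretch of each gene's transcript, from 10 ng of RNA and with 13 PCR cycles. The deposited table holds counts per gene, which per the file headers are whole-number counts and were not normalised; every library had a different total. The submitters' processing notes name hg19 as the genome build and DESeq2 as a tool without saying what each was used for. The aligner and the counting tool were not given in the sources used here, nor was it stated whether counting used strand. Because each gene is read from an amplicon, gene length does not scale the counts, but an amplicon may fail.

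The table had 20812 entries, of which 10 were spike-in controls and were left out. The symbols of 28 genes had been turned into dates; these were kept in the totals and tests, but they were not named, and 2 of the date names occurred for 2 genes. In each library the date-named genes held between 0.168% and 0.321% of the counts. Of the 20802 genes, 2252 had 0 counts in all libraries. Values of 65 genes were not written out.

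Libraries were grouped by the stage in the labels, with 3 per group. Genes were filtered with filterByExpr, which left 13792, and libraries were scaled by TMM. The quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 was fitted to all 9 libraries together, with a common biological coefficient of variation of 0.172. The comparisons were NCC aggregates against iPSCs, mdEM against NCC aggregates, mdEM against iPSCs, and any difference among the 3 stages. The p-values were adjusted by Benjamini-Hochberg over the tested genes of each comparison, with a threshold of 0.05. Levels are in CPM, counts relative to the TMM-scaled library total, as mean and standard deviation. Log2 fold changes carry approximate standard errors (SE). These were derived as the size of the log2 fold change over the square root of its F statistic, not estimated by the fit.

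Before the data were examined, the comparisons, the gene lists, the rule for named genes and most alternative settings were fixed. The 33 lists covered pluripotency, the facial and neural crest programs, signal targets, stress and growth programs, and markers of other cell types. A list was tested with camera of limma 3.58.1, with a preset correlation of 0.01, if at least 5 of its genes passed the filter, which 30 did. Listed genes that were not measured or had too few counts were not tested. This left 17 of 28 ectomesenchyme regulators, 8 of 16 CNS progenitor genes and 5 of 15 mesoderm genes, so statements on a list cover its tested genes only. The p-values of camera were adjusted over the lists of each comparison. Of the listed symbols 5 were not in the table and 3 were matched by an older symbol.

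The rule for named genes took, in NCC aggregates against iPSCs and in mdEM against NCC aggregates, the 4 largest rises and the 4 largest falls among genes past the threshold with at least 20 CPM in the higher group and no overlap between the libraries of the groups. From each list marked for a comparison it took up to 2 members past the threshold with the largest change and at least 10 CPM in the higher group. POU5F1, NANOG, SOX2, TFAP2A, PAX3, SOX10, FOXD3 and NGFR were always named in the first comparison. SOX10, FOXD3, TWIST1, PRRX1, PDGFRA, DLX5, DLX6, HAND1, HAND2, EDNRA and BARX1 were always named in the second. In mdEM against iPSCs, only genes named in the others were named by the rule. Some genes that the rule or a list would name are not reported here.

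A group with 0 counts for a gene was given a floor of 3 counts over the group, which is 0.129 CPM in iPSCs, 0.0849 CPM in NCC aggregates and 0.0872 CPM in mdEM. With 1 to 3 counts in a group, the ratio of CPM is given with an exact 95% counting interval.

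The pipeline was tested on simulated data with 200 changed genes among 13792. In NCC aggregates against iPSCs, 10.4% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 95.5% of those changed 4-fold were recovered, with 7 false calls. In mdEM against NCC aggregates the shares were the same, with 8 false calls. In mdEM against iPSCs the shares were 14.9%, 59.7% and 87.9%, with 4 false calls. Far more genes were called in the data, so the adjusted threshold was stricter in the simulation and these shares may not carry over. Each simulated gene had the same spread in all 3 groups. In the data the biological coefficient of variation was 0.0573 in iPSCs, 0.201 in NCC aggregates and 0.209 in mdEM. The false calls in the simulation therefore do not show what sharing 1 spread among these groups does. Among 30 simulated lists of 15 genes, camera called the changed list and 0 others in each comparison. The simulated genes were drawn independently, so this did not test camera on correlated list members. In the data the estimated correlation of the epithelial adhesion list was 0.609 in mdEM against NCC aggregates.

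The alternatives were DESeq2 size factors, library totals alone, upper-quartile scaling, no filter and a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom, a replicate block, only the libraries of the groups compared, a minimum fold of 2, libraries thinned to the smallest total, an estimated list correlation, fry, and leaving out each library in turn. Leaving out replicate 2 of both aggregate groups, a spread per group, and offsets for transcript GC content in 20 bins were chosen after seeing the data. A GC value was available for 13406 tested genes (97.2%). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.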

Results

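RNA was measured in 9 libraries from 3 stages of a stepwise culture of 1231A3, a human induced pluripotent stem cell (iPSC) line, with 3 libraries per stage. The starting iPSCs were sampled on day 0 of adherent culture. On day 5 the cells had become floating neural crest cell (NCC) aggregates. These had received the TGF-beta receptor inhibitor SB431542 (10 µM) from day 1, the growth factor BMP4 from day 1 to day 2, and the GSK-3 inhibitor CHIR99021 (1 µM), which activates WNT signalling, from day 2. The last samples, called mandibular prominence ectomesenchyme (mdEM), were aggregates cultured from day 5 to day 9 with FGF8b (100 ng/ml), endothelin-1 (50 nM) and BMP4 (2.5 ng/ml). Ectomesenchyme is the neural crest derived mesenchyme of the face, and the mandibular prominence is the embryonic tissue that forms the lower jaw. Expression was read with a targeted panel that amplifies a short stretch of each gene's transcript by PCR. The total counts were 7150110, 8883995 and 8112151 in the iPSC libraries, 11406967, 10935169 and 12944651 in the NCC aggregate libraries, and 11291844, 11065698 and 10927792 in the mdEM libraries. Between 15287 and 15970 genes had at least 1 count in a library. The labels do not say that the replicates of a stage came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

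The stages separated along the first 2 principal components of the tested genes, which carried 70.6% and 21.5% of the variance. Component 3, with 3.00%, separated replicate 2 of the NCC aggregates and replicate 2 of mdEM from the other libraries of their groups. Of 13792 genes tested, 11175 (81.0%) differed among the 3 stages (edgeR quasi-likelihood F-test, Benjamini-Hochberg adjusted p under 0.05). The biological coefficient of variation (BCV) within a group was 0.0573 in iPSCs, 0.201 in NCC aggregates and 0.209 in mdEM.

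**Figure D1:**
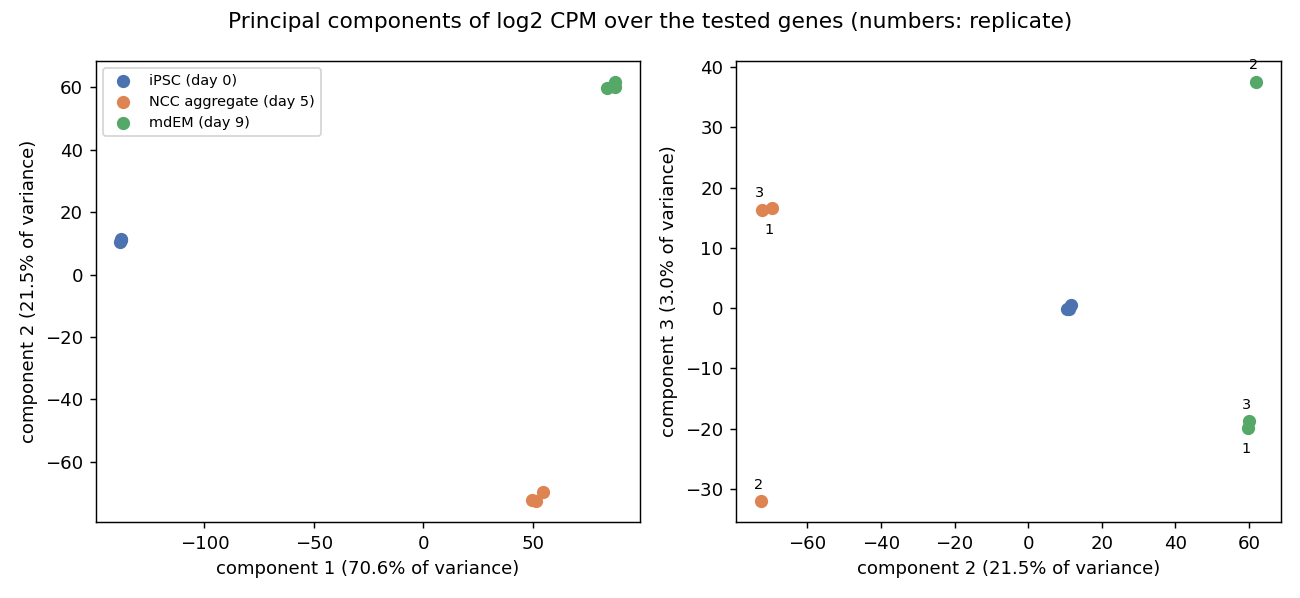
Principal components of the log2 CPM of the tested genes, with components 1 and 2 on the left and components 2 and 3 on the right, in arbitrary units; each point is 1 library, coloured by stage, and numbers give the replicate. The stages lie apart on components 1 and 2 (70.6% and 21.5% of the variance), while replicate 2 of each aggregate group lies apart from its group on component 3 (3.00%).

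The first comparison, NCC aggregates against iPSCs, shows what changed over the neural crest induction. Pluripotency transcripts fell and transcripts of the neural plate border and neural crest rose. POU5F1, the OCT4 transcription factor at the core of pluripotency, fell from 2664 ± 135 CPM (SD, n = 3) in iPSCs to 6.61 ± 0.707 CPM in NCC aggregates, a log2 fold change of -8.65 ± 0.32 (SE). SOX10, a transcription factor of migrating neural crest cells, rose from 1.62 ± 0.239 to 667 ± 146 CPM (log2 fold change 8.67 ± 0.24). EPCAM, an adhesion molecule of epithelial and pluripotent cells, fell from 568 ± 32.2 to 2.50 ± 1.07 CPM (log2 fold change -7.80 ± 0.39).

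The largest rises by the rule for named genes were those of TFAP2B, KANK4, NPR3 and RELN. TFAP2B, an AP-2 transcription factor of neural crest, had 0 counts in iPSCs and 555 ± 40.9 CPM in NCC aggregates, at least 4303-fold higher against a floor of 3 counts over the group. Such floors and the intervals below cover counting error only, since PCR reads without molecular identifiers are not independent molecules. KANK4 and RELN also had 0 counts in iPSCs and were at least 1012-fold and 617-fold higher by the same floor. NPR3, the natriuretic peptide clearance receptor, had 1 count in iPSCs and 439 ± 119 CPM in NCC aggregates, a ratio of 10299 with a 95% counting interval of 1837 to 404402. The largest falls were those of TDGF1, LCK, FOXH1 and IDO1. TDGF1, a co-receptor for Nodal, fell from 836 ± 17.3 CPM to 1 count in all, a ratio of 27053 (interval 5302 to 1167020). FOXH1, the DNA-binding partner of Nodal-activated SMADs, fell from 68.3 ± 5.25 CPM to 1 count in all, a ratio of 2637 (433 to 95493). LCK fell at least 719-fold to 0 counts, and IDO1 fell to 1 count in all, with a ratio of 1514 (248 to 54850).

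Gene lists fixed beforehand were tested with camera, which compares a list's members with all other genes tested. List members named below because few members went that way were chosen after their values were seen. Of the 20 tested genes of the pluripotency list, 17 fell and 2 rose (camera, adjusted p = 2.51e-22, a call that held with an estimated correlation). NANOG fell from 386 ± 13.9 to 7.05 ± 4.42 CPM (log2 fold change -5.78 ± 0.33, or -6.40 without NCC aggregate replicate 1), and GDF3 fell at least 151-fold to 0 counts. The 2 that rose were LIN28A and LIN28B, RNA-binding proteins that restrain let-7 microRNAs. SOX2, which marks pluripotent and neural cells alike, was at 91.3 ± 12.5 CPM in iPSCs and 105 ± 29.9 CPM in NCC aggregates and did not pass the test (log2 fold change 0.20 ± 0.20, edgeR adjusted p = 0.385). Without NCC aggregate replicate 2 its log2 fold change of 0.42 did pass (edgeR adjusted p = 0.0197). Of 11 tested Nodal and activin targets, 9 fell and 1 rose (camera, adjusted p = 2.57e-08, also held with an estimated correlation).

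In the neural plate border list 11 of 14 genes rose and 3, ZIC2, ZIC5 and GBX2, fell (camera, adjusted p = 1.62e-07, held with an estimated correlation). PAX3, a paired-box regulator of the border, rose from 0.172 ± 0.0733 to 334 ± 14.8 CPM (log2 fold change 10.83 ± 0.22). TFAP2A, another AP-2 factor, had 3 counts in iPSCs and 388 ± 49.3 CPM in NCC aggregates, a ratio of 2872 (95% counting interval 1027 to 14555). In the neural crest specifier list 16 of 19 genes rose and 2, ETS1 and MYC, fell (camera, adjusted p = 9.53e-10, held with an estimated correlation). NCC aggregate replicate 2 was the lowest of its group in 11 of the 19 and the highest in 6. The adhesion molecule CDH6 rose from 1.88 ± 0.227 to 1334 ± 232 CPM, and NGFR, the low-affinity neurotrophin receptor used to sort neural crest cells, from 5.87 ± 1.11 to 189 ± 79.1 CPM. FOXD3, a regulator shared by pluripotent and neural crest cells, rose from 39.1 ± 1.64 to 152 ± 17.0 CPM (log2 fold change 1.95 ± 0.26).

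Epithelial transcripts fell together and mesenchymal ones mostly rose. All 19 tested genes of the epithelial adhesion list fell (camera, adjusted p = 3.07e-21, held with an estimated correlation), CLDN7 from 172 ± 10.9 to 1.22 ± 0.418 CPM. Among the 3 NCC aggregate libraries, 18 of these 19 genes were lowest in replicate 2 and 13 highest in replicate 1. Of 23 mesenchyme and matrix genes 16 rose and 5 fell, the last being COL1A1, COL6A2, THY1, TGFBI and LOX (camera, adjusted p = 6.91e-05; adjusted p = 0.111 with an estimated correlation). ZEB2 and ZEB1, which repress epithelial genes, were both higher. ZEB2 had 2 counts in iPSCs and 238 ± 25.7 CPM in NCC aggregates, a ratio of 2791 (766 to 22858), and ZEB1 rose from 0.477 ± 0.0966 to 16.8 ± 5.52 CPM.

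Targets of the signals in the protocol moved apart. Of 13 WNT targets 9 rose and 2, ZNRF3 and FZD7, fell (camera, adjusted p = 0.00197; adjusted p = 0.143 with an estimated correlation). In NCC aggregate replicate 2, 10 of the 13 were the highest of the group. TNFRSF19 rose from 1.20 ± 0.290 to 118 ± 9.93 CPM. SP5, a direct WNT target, had 2 counts in iPSCs and 7.37, 42.8 and 11.6 CPM in NCC aggregate replicates 1 to 3. Of 17 BMP targets 13 rose and 3, ID1, SMAD7 and BAMBI, fell (camera, adjusted p = 0.00101; adjusted p = 0.283 with an estimated correlation). Of the 3 NCC aggregate libraries, replicate 1 was the highest in 14 of these 17 genes. The homeobox gene MSX2 rose from 0.425 ± 0.166 to 52.9 ± 29.9 CPM, and MSX1 was at least 81.9-fold higher, with 0 counts in iPSCs. Of 15 FGF targets 10 fell and 1, SPRED2, rose (camera, adjusted p = 1.62e-07, held with an estimated correlation).

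Genes of the facial programs had begun to rise at day 5. The ectomesenchyme regulators had 9 of 17 genes higher and 3, PRRX2, LHX8 and BARX1, lower (camera, adjusted p = 0.00163; adjusted p = 0.0819 with an estimated correlation). NR2F1, a nuclear receptor of cranial neural crest, went from 3 counts in iPSCs to 416 ± 27.8 CPM, a ratio of 3253 (1107 to 15686), and NR2F2 from 2 counts to 134 ± 46.4 CPM, a ratio of 1572 (439 to 13100). The mandibular and endothelin-DLX list had 9 of 15 genes higher and 2, BARX1 and GBX2, lower (camera, adjusted p = 0.000105; adjusted p = 0.159 with an estimated correlation), and 10 of the 15 were highest of their group in NCC aggregate replicate 1. Of the 6 tested genes of the maxillary list POU3F3, NR2F1, NR2F2 and MEIS2 rose while FOXL2 and CYP26A1 fell (camera, adjusted p = 0.00197). This call was lost with an estimated correlation (camera, adjusted p = 0.0553) and with a replicate block (camera, adjusted p = 0.0624). The estimated correlation was -0.124, below the preset of 0.01, so correlation between members was not what ended the call in the first of these settings. In the frontonasal list 3 of 6 genes, ALX1, PAX7 and PAX3, rose (camera, adjusted p = 0.000264, held with an estimated correlation).

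Markers of other cell types were measured beside these. In the neuron list 16 of 18 genes rose (camera, adjusted p = 2.50e-06; adjusted p = 0.171 with an estimated correlation), and 13 of the 18 were lowest in NCC aggregate replicate 2 and 13 highest in replicate 3 of that group. Of 9 glia and melanocyte genes 7 rose and 1, MBP, fell (camera, adjusted p = 0.00158, or 0.143 with an estimated correlation). NCC aggregate replicate 3 was the highest of its group in 6 of these 9. Of 12 chondrocyte genes 8 rose and 4, COL9A3, MATN3, MATN4 and LECT1, fell (camera, adjusted p = 0.0110; adjusted p = 0.125 with an estimated correlation). Of 10 smooth muscle and pericyte genes 6 fell and 3, ACTA2, MYLK and LMOD1, rose (camera, adjusted p = 0.0208; adjusted p = 0.116 with an estimated correlation). Hypoxia and glycolysis genes had 9 of 19 lower and 5 higher, BNIP3, P4HA1, KDM3A, PFKFB4 and HK2 (camera, adjusted p = 0.00914; adjusted p = 0.289 with an estimated correlation). Among the NCC aggregate libraries 14 of the 19 were lowest in replicate 2 and 15 were highest in replicate 3.

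Several lists did not pass camera in this comparison. In the CNS progenitor list PAX6, FABP7, LHX5, EMX2 and OTX2 rose and SOX3 and SIX6 fell (8 tested; camera, adjusted p = 0.708). FABP7, a fatty acid binding protein of radial glia and crest derived glia, rose from 25.5 ± 3.87 to 122 ± 17.2 CPM, while SOX3 fell from 53.3 ± 3.56 to 4.25 ± 1.29 CPM. In the surface ectoderm and placode list GRHL3, EYA2, DLX3 and PAX2 rose and 5 others, among them PERP, SIX4 and CLDN1, fell (9 tested; camera, adjusted p = 0.969), with a median log2 fold change of -0.84 and a mean of 1.34. EYA2 rose from 2.57 ± 0.461 to 49.5 ± 37.1 CPM (log2 fold change 4.26 ± 0.60, or 3.43 without NCC aggregate replicate 3). Of the 9 genes in this list, 6 were highest in NCC aggregate replicate 1 and 6 lowest in replicate 2. DLX3 had 2 counts in iPSCs and 31.8 ± 12.9 CPM in NCC aggregates, a ratio of 406 (103 to 3072). In the amnion and trophectoderm list ISL1, GATA2, GATA3 and TFAP2C rose and KRT7 and IGFBP3 fell (6 tested; camera, adjusted p = 0.243). TFAP2C, which also serves the neural plate border, rose from 3.73 ± 0.838 to 109 ± 24.6 CPM, and IGFBP3 fell from 11.3 ± 1.70 to 4.80 ± 2.12 CPM. Of 24 cell cycle genes 10 fell and 5, MKI67, TOP2A, BUB1, CENPF and TYMS, rose (camera, adjusted p = 0.850). Of 8 osteoblast and tooth mesenchyme genes 2, among them DLX3, rose and ALPL, SPP1 and COL1A1 fell (camera, adjusted p = 0.147), with a median log2 fold change of -0.56 (-0.61 with genes at 0 set to their bound) and a mean of 0.19.

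By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4952 genes were higher and 4424 lower in NCC aggregates, 68.0% of those tested, and 3155 and 2745 of them by at least 2-fold. Without replicate 2 of the NCC aggregates and of mdEM, a choice made after seeing the data, the counts were 5560 and 5148. Adjusted over the list alone, the counts of called members were the same in these lists, except 17 neuron genes higher and 6 hypoxia genes higher. The medium also lost basic FGF and the cells went from adherent to floating culture between these stages, so the comparison holds all of these changes together.

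The second comparison, mdEM against NCC aggregates, shows what changed over the culture with FGF8b, endothelin-1 and BMP4. Regulators of ectomesenchyme and of the mandibular prominence rose, and neural crest and glial transcripts fell. HAND2, a transcription factor downstream of endothelin in the lower jaw, went from 1 count in all NCC aggregate libraries to 479 ± 96.6 CPM (SD, n = 3) in mdEM, a ratio of 16754 with a 95% counting interval of 3032 to 667392. TWIST1, which drives mesenchymal fate in cranial crest, rose from 5.09 ± 1.59 to 372 ± 129 CPM (log2 fold change 6.19 ± 0.32, SE). SOX10 fell from 667 ± 146 to 30.0 ± 2.83 CPM (log2 fold change -4.48 ± 0.18), which left it above its iPSC level of 1.62 ± 0.239 CPM.

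The largest rises by the rule were those of BARX1, HAND2, NBLA00301 and SYNPO. BARX1, a homeobox gene of tooth and jaw mesenchyme, had 0 counts in NCC aggregates and 152 ± 7.96 CPM in mdEM, at least 1794-fold higher against 3 counts over the group. NBLA00301, a symbol for the antisense transcript next to HAND2, was at least 1311-fold higher; the counting is not stated to use strand, so its reads were not separated from any of HAND2 that overlap them. SYNPO, an actin-associated protein, went from 1 count to 40.9 ± 4.61 CPM, a ratio of 1579 (259 to 57090). The largest falls were those of SP5, PRDM12, NEUROG1 and FOXD3. SP5, at 7.37, 42.8 and 11.6 CPM in NCC aggregate replicates 1 to 3, fell to 1 count in mdEM, a ratio of 695 (121 to 26837), or 320 (58.5 to 13060) without NCC aggregate replicate 2. PRDM12, a regulator of pain-sensing neurons, fell from 69.1 ± 27.1 to 0.376 ± 0.3003 CPM (log2 fold change -7.47 ± 0.46, or -8.22 without mdEM replicate 1). NEUROG1, a determination factor of sensory neurons, fell from 20.5 ± 6.03 to 0.175 ± 0.230 CPM (log2 fold change -6.78 ± 0.55, or -8.52 without mdEM replicate 2), and FOXD3 fell to 1.43 ± 1.08 CPM.

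**Figure D2:**
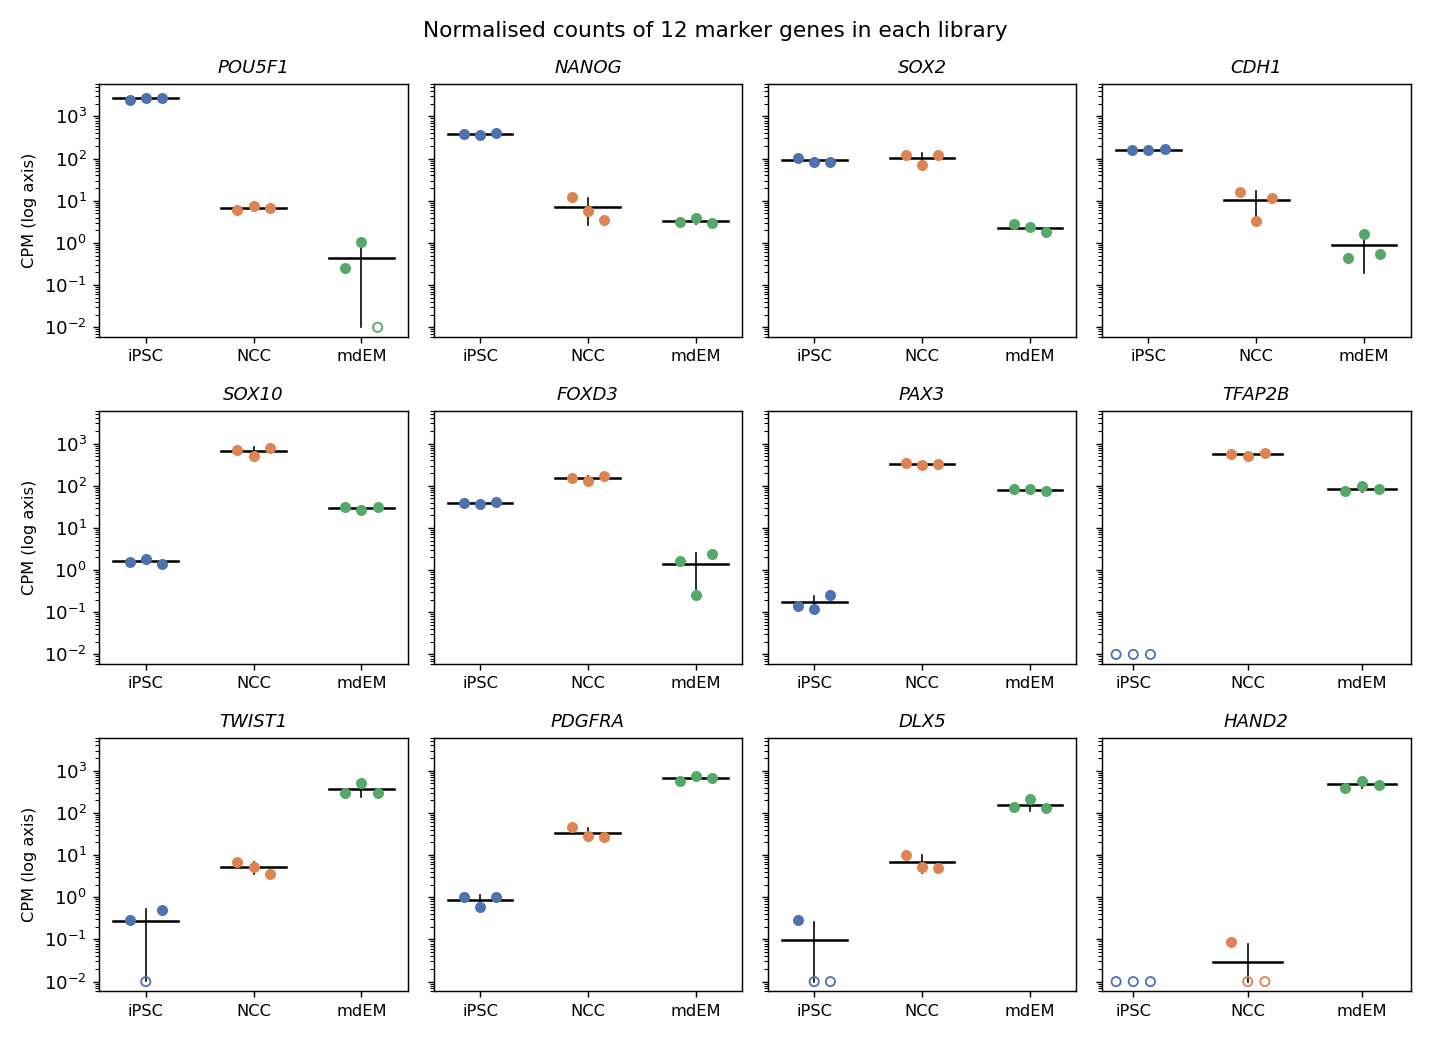
Normalised counts (CPM, log axis) of 12 genes in each of the 9 libraries by stage; filled points are libraries, open points at the foot of the axis are libraries with 0 counts, horizontal bars are group means and vertical bars are 1 SD, drawn down to the foot of the axis where they reach 0 or below. POU5F1 fell from 2664 to 6.61 CPM by the NCC stage, SOX10 was highest there at 667 CPM, and HAND2 reached 479 CPM in mdEM.

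Of 17 tested ectomesenchyme regulators 15 rose and none fell (camera, adjusted p = 6.54e-30, held with an estimated correlation), while NR2F1 and NR2F2 did not pass the test. PDGFRA, the receptor that marks facial mesenchyme, rose from 34.3 ± 10.6 to 665 ± 102 CPM (log2 fold change 4.28 ± 0.22). PRRX1, a homeobox gene of craniofacial and limb mesenchyme, had 1 count in NCC aggregates and 9.35, 25.0 and 6.93 CPM in mdEM replicates 1 to 3. Of 15 genes of the mandibular and endothelin-DLX list 13 rose and 2, EDNRA and TBX3, fell (camera, adjusted p = 1.85e-19, held with an estimated correlation). DLX5 rose from 6.81 ± 3.01 to 157 ± 44.7 CPM and DLX6, its partner in specifying the lower jaw, from 0.475 ± 0.575 to 118 ± 24.6 CPM (log2 fold change 7.91 ± 0.45, or 9.35 without NCC aggregate replicate 1). EDNRA, the endothelin receptor itself, fell from 822 ± 164 to 199 ± 28.96 CPM (log2 fold change -2.05 ± 0.18), still above 1.76 ± 0.659 CPM in iPSCs. HAND1 was not tested for want of counts, with 21 counts over the NCC aggregates and 3 over mdEM. Among the 3 mdEM libraries, 10 of the 15 mandibular genes were highest in replicate 2, and among the NCC aggregates 10 were highest in replicate 1.

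The lists of the other facial prominences did not pass camera. In the maxillary list 1 of 6 genes, MEIS2, rose, from 46.7 ± 5.06 to 264 ± 29.7 CPM (camera for the list, adjusted p = 0.249). In the frontonasal list 4 of 6 genes, among them ALX1, ALX4 and SIX2, rose and PAX7 and PAX3 fell (camera, adjusted p = 0.742), and 5 of the 6 were lowest of the group in mdEM replicate 3. ALX4 went from 3 counts to 20.8 ± 3.08 CPM, a ratio of 251 (83.6 to 1192), and PAX7 from 18.1 ± 2.90 CPM to 2 counts, a ratio of 316 (85.3 to 2562). None of the 38 measured HOX genes, which mark crest from behind the first pharyngeal arch and the trunk, had enough counts to be tested. All 38 together had between 0 and 17 counts per library, at most 1.48 CPM. At least 1 count was seen for 17 of them, the most for HOXC6 with 18 over mdEM. The other 21 had 0 counts in every library, so no stage showed that their amplicons work.

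Targets of the signals moved with the change of factors. Of 15 FGF targets 10 rose and 1, EGR1, fell (camera, adjusted p = 3.24e-12, held with an estimated correlation). The fall of EGR1 leaned on NCC aggregate replicate 2, with 64.2 CPM against 5.14 and 6.21 CPM in replicates 1 and 3, and its log2 fold change of -3.70 ± 0.89 became -1.56 ± 0.42 without that library. In mdEM replicate 2, 10 of the 15 FGF targets were the highest of the group. DUSP6, a phosphatase that limits ERK, rose from 6.03 ± 1.49 to 155 ± 35.3 CPM after 277 ± 17.6 CPM in iPSCs, and ETV4 from 0.675 ± 0.221 to 16.7 ± 3.38 CPM after 154 ± 8.34 CPM. Of 17 BMP targets 10 rose and 2, NOG and BMPER, fell (camera, adjusted p = 5.85e-06; adjusted p = 0.132 with an estimated correlation). ID1, a direct BMP target, rose from 30.5 ± 14.8 to 299 ± 91.5 CPM. Of 13 WNT targets 10 fell and 1, DKK1, rose (camera, adjusted p = 2.89e-06, held with an estimated correlation). DKK1, a secreted WNT inhibitor, rose from 0.230 ± 0.0657 to 35.1 ± 23.8 CPM.

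Of 19 neural crest specifiers 13 fell and 3, SNAI1, TWIST1 and MYC, rose (camera, adjusted p = 9.82e-07, held with an estimated correlation). In the neural plate border list 8 of 14 genes fell and 4, MSX1, MSX2, DLX3 and GBX2, rose (camera, adjusted p = 0.000118, held with an estimated correlation). Of 18 neuron genes 13 fell and 2, DCX and PRPH, rose (camera, adjusted p = 0.000110; adjusted p = 0.268 with an estimated correlation), NEUROD4 from 42.5 ± 21.4 to 1.68 ± 0.556 CPM. Of 9 glia and melanocyte genes 6 fell and 1, CDH19, rose (camera, adjusted p = 6.25e-07, held with an estimated correlation). S100B fell from 98.5 ± 4.03 to 1.43 ± 0.570 CPM. In mdEM replicate 2, 13 of the 18 neuron genes and 8 of the 9 glia and melanocyte genes were the lowest of the group, while 13 neuron genes and 6 glia and melanocyte genes were the highest in mdEM replicate 1. Of 8 CNS progenitor genes 6 fell (camera, adjusted p = 0.000203, held with an estimated correlation). In the pluripotency list 13 of 20 genes fell and 1, DPPA2, rose (camera, adjusted p = 5.84e-07, held with an estimated correlation). Of these 20 genes, 14 were lowest in mdEM replicate 3 and 10 highest in mdEM replicate 2.

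Of 23 mesenchyme and matrix genes 18 rose and 2, CDH2 and ZEB2, fell (camera, adjusted p = 3.26e-19, held with an estimated correlation). Within mdEM, 13 of the 23 were lowest in replicate 2 and 12 highest in replicate 3. LUM, a matrix proteoglycan, rose from 3.51 ± 1.97 to 369 ± 32.8 CPM and COL3A1 from 0.825 ± 0.0886 to 60.7 ± 35.5 CPM. Of 8 osteoblast and tooth mesenchyme genes 6 rose and 2, ALPL and SPP1, fell (camera, adjusted p = 5.84e-07, held with an estimated correlation), and 6 of the 8 were highest of their group in mdEM replicate 2. COL1A1 rose from 9.18 ± 0.789 to 403 ± 49.2 CPM, and PTH1R, the parathyroid hormone receptor, from 0.176 ± 0.172 to 88.3 ± 23.6 CPM (log2 fold change 8.92 ± 0.43, or 9.83 without NCC aggregate replicate 1 and 8.33 without replicate 3). Of 10 smooth muscle and pericyte genes 6 rose (camera, adjusted p = 0.00401, held with an estimated correlation), RGS5 from 8.96 ± 2.97 to 52.9 ± 19.8 CPM and CSPG4 from 0.947 ± 0.296 to 15.5 ± 7.72 CPM, with 6 of the 10 highest of their group in mdEM replicate 2. Of 12 chondrocyte genes SOX6 and COL2A1 rose and COL9A1, COL9A3, COL11A2 and LECT1 fell (camera, adjusted p = 0.540), with a median log2 fold change of 0.19 and a mean of -0.41. COL11A2, a cartilage collagen, fell from 60.5 ± 23.7 to 3.98 ± 2.98 CPM (log2 fold change -3.92 ± 0.43, or -4.73 without mdEM replicate 2), and LECT1 from 15.9 ± 1.79 to 2.19 ± 1.42 CPM. Of 19 epithelial adhesion genes 13 fell and 1, DSP, rose (camera, adjusted p = 2.61e-05; adjusted p = 0.315 with an estimated correlation). KRT19 fell from 15.1 ± 7.83 to 0.814 ± 0.579 CPM and CDH1 from 10.3 ± 6.56 to 0.872 ± 0.679 CPM, and their log2 fold changes of -4.20 ± 0.49 and -3.56 ± 0.56 became -4.95 and -4.40 without mdEM replicate 2, the library in which 11 of the 19 epithelial genes were highest of their group.

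Of 24 cell cycle genes 14 fell and none rose (camera, adjusted p = 0.000686; adjusted p = 0.226 with an estimated correlation). Within their groups, 18 of the 24 were lowest in mdEM replicate 2 and 15 were highest in NCC aggregate replicate 2. MCM5, a replication licensing factor, fell from 174 ± 44.7 to 65.0 ± 13.1 CPM and E2F1 from 98.4 ± 8.86 to 39.3 ± 6.70 CPM. Among 19 hypoxia and glycolysis genes 9 fell and 5, VEGFA, NDRG1, PDK1, ALDOC and PFKFB3, rose (camera, adjusted p = 0.244). The hexokinase HK2 fell from 90.1 ± 21.6 to 22.2 ± 7.01 CPM and the glucose transporter SLC2A1 from 205 ± 72.8 to 63.9 ± 9.29 CPM. In the surface ectoderm and placode list SIX4 and DLX3 rose and 5 of 9 genes, among them GRHL3, EYA2 and CLDN1, fell (camera, adjusted p = 0.0708).

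**Figure D3:**
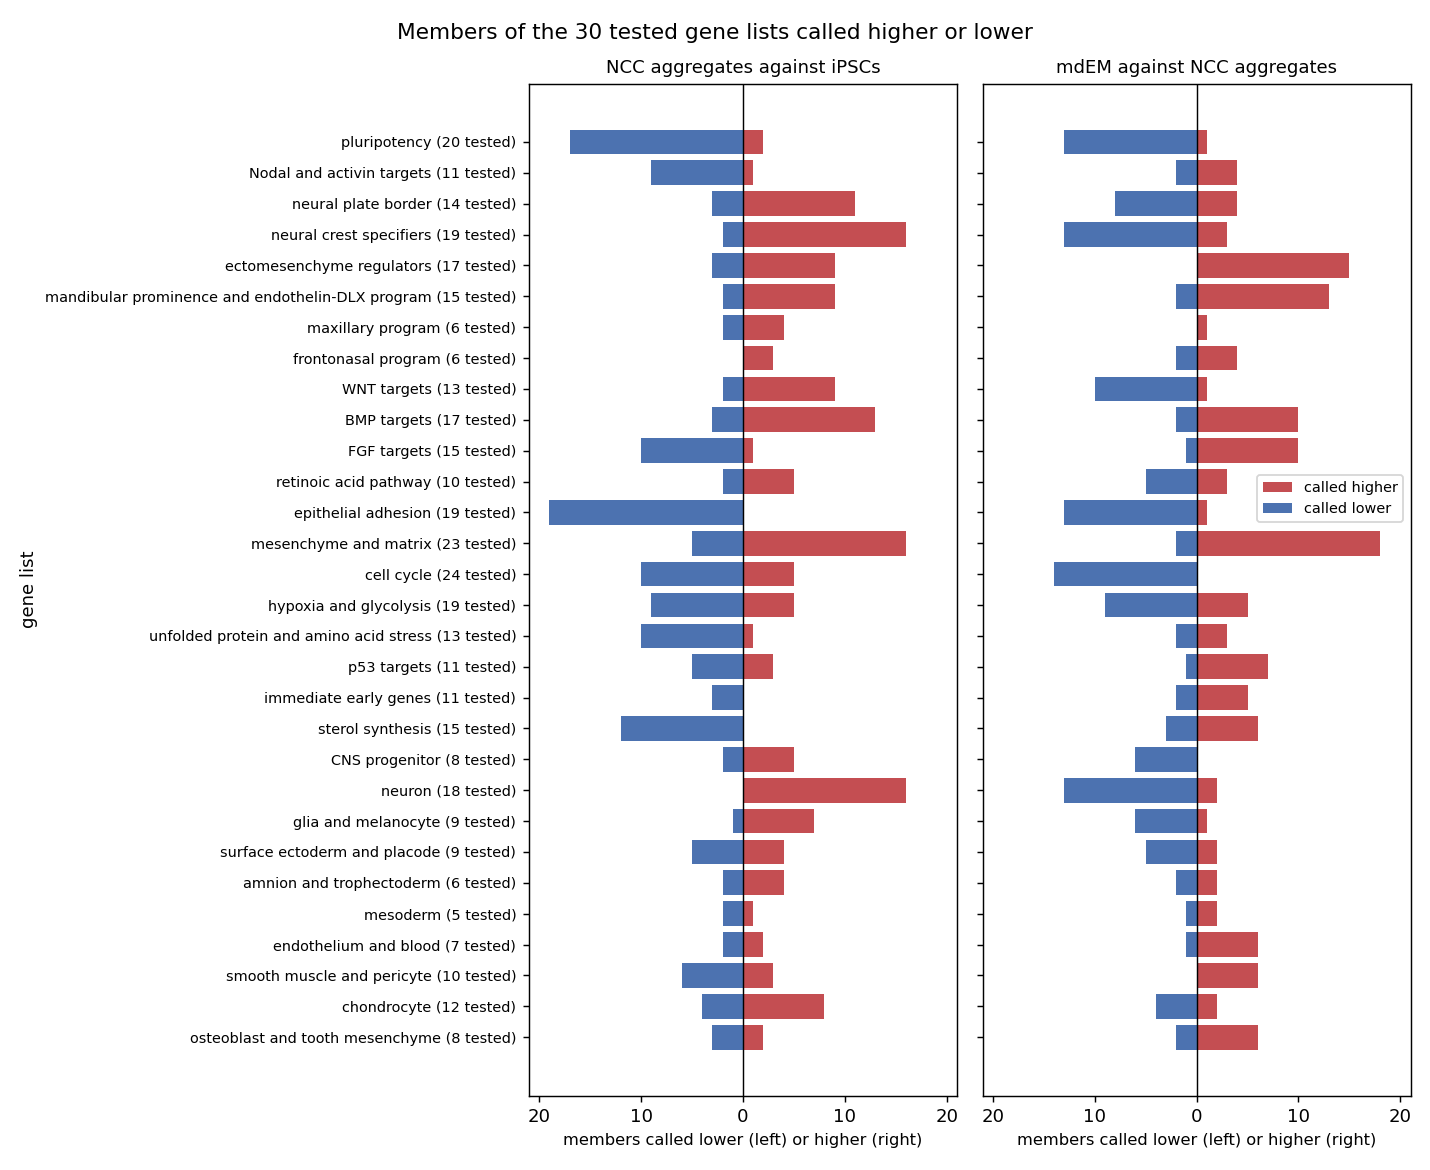
Members of the 30 tested gene lists called higher (bars to the right) or lower (bars to the left) in NCC aggregates against iPSCs and in mdEM against NCC aggregates; the horizontal axes count genes and the labels give the genes tested. In the second comparison 15 of 17 ectomesenchyme regulators were higher and none lower, and 13 of 19 neural crest specifiers were lower.

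By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2876 genes were higher and 2733 lower in mdEM than in NCC aggregates, 40.7% of those tested, and 1716 and 1187 of them by at least 2-fold. Without replicate 2 of both groups, chosen after seeing the data, the counts were 3985 and 4017. The fit shared 1 spread among all 3 groups, and the iPSC libraries lay closer together than those compared here. That fit called 5609 genes, against 4379 with only the libraries of the groups compared and 4811 with a replicate block. With a spread per group, also chosen after seeing the data, 4751 were called, and with GC offsets 5840. Adjusted over the list alone, the counts of called members differed from these in 6 of the lists above: 15 pluripotency, 14 epithelial, 7 CNS progenitor and 7 surface ectoderm genes were lower, and 11 BMP targets and 20 mesenchyme genes higher. The 3 added factors and the removal of CHIR99021 and SB431542 came together with 4 more days of culture, so the comparison does not separate them.

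Putting both steps together gave the course of each gene. At day 5, 994 genes were higher than at both other stages and 1055 were lower than at both. Among the first were SOX10, FOXD3, NGFR, PAX3, TFAP2B, CDH6 and EDNRA, and among the second DUSP6, ETV4, RGS5, COL1A1 and BARX1. Independent lists of the same sizes would share 981 and 923 genes. A further 1019 genes rose in both steps, among them TWIST1, PDGFRA, DLX5, MSX2 and LUM, and 965 fell in both, among them POU5F1, NANOG, EPCAM, CDH1 and KRT19, against 1033 and 877 for independent lists. The NCC libraries enter both steps, and in 20 simulations without any effect the log2 fold changes of the steps had a mean correlation of -0.48 and covariance of -0.04, against -0.15 and -0.44 observed across genes, which are not independent replicates. These simulations, in which each gene had the same spread in all 3 groups, gave at most 1 gene in either course. The 3 NCC libraries could not be split into parts of at least 2, so part of the opposite movement may come from the shared libraries. Without replicate 2 of both aggregate groups the 994 and 1055 genes became 1817 and 1601.

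The last comparison, mdEM against iPSCs, spans both steps and is not independent of them. Of the 28 listed ectomesenchyme regulators 17 were tested, and all 17 were higher in mdEM (camera, adjusted p = 1.83e-18, held with an estimated correlation). A gene near 0 in iPSCs passed the filter only if a later stage expressed it, so among such genes the filter favoured rises. Higher too were 14 of 15 mandibular genes and 20 of 23 mesenchyme and matrix genes (camera, adjusted p = 7.29e-17 for both, held with an estimated correlation). Of 20 pluripotency genes 18 were lower and 1, LIN28B, higher (camera, adjusted p = 2.89e-27, held with an estimated correlation), and 18 of 19 epithelial genes were lower (camera, adjusted p = 5.87e-23; adjusted p = 0.0831 with an estimated correlation). SOX2 fell from 91.3 ± 12.5 to 2.32 ± 0.440 CPM and POU5F1 to 0.434 ± 0.544 CPM, the latter with a log2 fold change of -12.54 ± 0.40, or -14.18 without mdEM replicate 2. TFAP2A stayed high, with 3 counts in iPSCs and 278 ± 52.2 CPM in mdEM, a ratio of 2055 (738 to 10458).

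In the frontonasal list 5 of 6 genes were higher and none lower (camera, adjusted p = 0.000206, held with an estimated correlation). In the maxillary list POU3F3, NR2F1, NR2F2 and MEIS2 were higher and FOXL2 and CYP26A1 lower (camera, adjusted p = 0.00240; adjusted p = 0.0573 with an estimated correlation). Of 17 BMP targets 14 were higher and none lower (camera, adjusted p = 2.63e-07; adjusted p = 0.146 with an estimated correlation), and of 11 Nodal and activin targets 2 were higher and 8 lower (camera, adjusted p = 4.88e-05, held with an estimated correlation). Of 18 neuron genes 13 were higher and 2, TUBB3 and NTRK3, lower (camera, adjusted p = 0.0349; adjusted p = 0.470 with an estimated correlation), with 13 of the 18 lowest of the group in mdEM replicate 2. In the neural plate border list 9 of 14 genes were higher and ZIC2 and ZIC5 lower (camera, adjusted p = 0.00541; adjusted p = 0.0831 with an estimated correlation). Of 19 hypoxia and glycolysis genes 11 were lower and 4, NDRG1, BNIP3, P4HA1 and KDM3A, higher (camera, adjusted p = 0.00293; adjusted p = 0.306 with an estimated correlation).

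Of 19 neural crest specifiers 12 were higher and 4, FOXD3, ETS1, MYC and MYCN, lower than in iPSCs (camera, adjusted p = 0.00293; adjusted p = 0.1002 with an estimated correlation). NGFR and S100B did not pass the test against iPSCs (edgeR adjusted p = 0.163 and 0.520), at 11.1 ± 8.49 and 1.43 ± 0.570 CPM in mdEM and 5.87 ± 1.11 and 1.67 ± 0.671 CPM in iPSCs. The log2 fold change of NGFR was 0.91 ± 0.57, or 0.22 without mdEM replicate 3. NGFR passed without mdEM replicate 1 (1.39). Of 15 FGF targets 6 were higher and 7 lower (camera, adjusted p = 0.399), with DUSP6 1.79-fold lower than in iPSCs, and 10 of the 15 were highest of the group in mdEM replicate 2. Of 24 cell cycle genes 17 were lower and 3, MKI67, TOP2A and CENPF, higher (camera, adjusted p = 0.0395; adjusted p = 0.429 with an estimated correlation), a call that ended without mdEM replicate 2 (camera, adjusted p = 0.0612).

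In all, 5253 genes were higher and 4740 lower in mdEM than in iPSCs (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Adjusted over the list alone, the counts of called members in this comparison differed in 4 lists. These were the neural crest specifiers, with 5 lower, and the cell cycle genes, with 4 higher. The sterol synthesis genes had 0 higher and 7 lower in place of 1 and 8. The immediate early genes had 4 higher and 7 lower in place of 3 and 6.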

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

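The settings that left out replicate 2 of both aggregate groups, gave each group its own spread, or removed GC content trends were chosen after seeing the data. Among the main counts of genes and lists, 271 values under an alternative stayed within 1.5 times the reported count, 10 were lower and 4 higher. With a minimum fold of 2, which asks for a larger change by construction, 2172 genes were higher and 2006 lower in NCC aggregates against iPSCs, 1036 and 600 in mdEM against NCC aggregates, and 2791 and 2296 in mdEM against iPSCs. With an estimated list correlation, 3 lists were higher and 4 lower in NCC aggregates against iPSCs, down from 12 and 8. In mdEM against iPSCs 4 were higher and 2 lower, down from 9 and 7. Correlation between members does not account for every lost call. The maxillary and smooth muscle lists lost theirs in NCC aggregates against iPSCs with estimates of -0.124 and -0.0504, below the preset of 0.01. So did the maxillary list in mdEM against iPSCs, with -0.0822. With fry, which does not compare a list with other genes, 15 lists were higher and 12 lower in mdEM against iPSCs. Without replicate 2 of both aggregate groups, 1817 genes were higher and 1601 lower at day 5 than at both other stages, and the cause was not tested.

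For named genes and lists, 4248 values kept their direction and side of the threshold, 33 passed it newly, 35 no longer passed and 42 reversed. The reversals were all in results that passed under neither setting, and their cause was not tested. In mdEM against iPSCs, leaving out each library in turn gave log2 fold changes of -2.999 to 1.79 for SP5 (turned without iPSC replicate 2), 0 to 3.02 for PAX7 (0 without mdEM replicate 1) and -0.50 to 0.073 for S100B (turned without iPSC replicate 2 and without mdEM replicate 2). S100B was at 0.031 without replicate 2 of both aggregate groups. For lists that turned, leaving out each library in turn gave adjusted p-values of 0.845 to 0.972 for surface ectoderm in NCC aggregates against iPSCs. In mdEM against NCC aggregates they were 0.763 to 0.997 for stress, 0.763 to 0.992 for amnion and 0.505 to 0.873 for mesoderm, and in mdEM against iPSCs 0.831 to 0.955 for retinoic acid and 0.760 to 0.981 for mesoderm. Without replicate 2 of both aggregate groups they were 0.540 for stress, 0.699 for amnion and 0.468 for mesoderm in mdEM against NCC aggregates, and 0.774 for retinoic acid and 0.723 for mesoderm in mdEM against iPSCs. With fry the stress list in mdEM against NCC aggregates turned at 0.802.

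With a replicate block the mesoderm list turned, with adjusted p = 0.880 in mdEM against NCC aggregates and 0.947 in mdEM against iPSCs, and the maxillary list in NCC aggregates against iPSCs lost its call (adjusted p = 0.0624). Deviations of libraries with the same replicate number had correlations of -0.288 to -0.00114 across genes over 9 pairs, so no shift shared by such libraries was seen. The labels do not say whether libraries with the same number were handled together, and these correlations cannot decide it. Depth limits genes near the floors, and changes of 1.5-fold were mostly missed in simulated data (10.4% recovered in both steps). The simulation changed only 200 of 13792 genes, while 68.0% and 40.7% were called in the 2 steps of the data. Its adjusted threshold was therefore stricter, and the recovered share may not carry over.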

Other observations

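The tests of GC content for the libraries that stood apart, of epithelial cells and of endothelial cells were chosen only after the results were seen. The genes named here were chosen after their values were seen. Among endothelium and blood genes, 6 of 7 rose in mdEM against NCC aggregates and 1, the angiopoietin receptor TEK, fell (camera, adjusted p = 0.000110, held with an estimated correlation). PLVAP, a protein of endothelial vesicles, rose from 0.652 ± 0.177 to 71.5 ± 10.9 CPM (SD, n = 3). In NCC aggregates against iPSCs PLVAP and CD34 rose and KDR and TIE1 fell (camera, adjusted p = 0.621). Retinoic acid pathway genes went both ways, with 5 of 10 higher and 2, CYP26A1 and DHRS3, lower in NCC aggregates against iPSCs (camera, adjusted p = 0.807), and CYP26B1, RARB and ALDH1A2 higher and 5 lower in mdEM against NCC aggregates (camera, adjusted p = 0.440). CRABP2, which carries retinoic acid in the cell, was at 67.0 ± 3.11 CPM in iPSCs, 2408 ± 330 CPM in NCC aggregates and 191 ± 104 CPM in mdEM.

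Of 13 unfolded protein and amino acid stress genes 10 fell and 1, SESN2, rose in NCC aggregates against iPSCs (camera, adjusted p = 0.00330; adjusted p = 0.146 with an estimated correlation). Of the 13, 9 were highest of the group in NCC aggregate replicate 2. ASNS, which makes asparagine, fell from 95.0 ± 8.70 to 23.6 ± 7.70 CPM. In mdEM against NCC aggregates TRIB3, SESN2 and VLDLR rose and ATF3 and PSAT1 fell (camera, adjusted p = 0.971), with a median log2 fold change of -0.04 and a mean of 0.17. Of 15 sterol synthesis genes 12 fell and none rose in NCC aggregates against iPSCs (camera, adjusted p = 0.00293; adjusted p = 0.306 with an estimated correlation), with 10 of the 15 lowest of the group in NCC aggregate replicate 3. At the second step 6 rose and 3, among them INSIG1 and MVD, fell (camera, adjusted p = 0.540). In mdEM against iPSCs 9 of 13 stress genes were lower and SESN2 and VLDLR higher (camera, adjusted p = 0.0118; adjusted p = 0.278 with an estimated correlation). Of the 15 sterol genes 8 were lower there (camera, adjusted p = 0.0383; adjusted p = 0.464 with an estimated correlation), a call that ended without mdEM replicate 3 (camera, adjusted p = 0.0529), where 9 of the 15 were lowest of the group, while 10 were highest in mdEM replicate 2. Of 11 p53 targets FAS, TP53INP1 and ZMAT3 rose and 5 fell at the first step (camera, adjusted p = 0.853), and 7 rose and 1, FAS, fell at the second (camera, adjusted p = 0.0708), with 7 of the 11 highest of the group in mdEM replicate 2. Of 11 immediate early genes IER3, ZFP36 and HSPA1B fell at the first step (camera, adjusted p = 0.175), and 5 rose and 2, EGR1 and ATF3, fell at the second (camera, adjusted p = 0.742), with a median log2 fold change of 0.34 and a mean of -0.30. EGR1 was at 5.14, 64.2 and 6.21 CPM in NCC aggregate replicates 1 to 3, and without replicate 2 it also fell at the first step (log2 fold change -1.07 ± 0.39, edgeR adjusted p = 0.0295). Of 5 mesoderm genes PAX2 rose and TCF15 and MYL7 fell at the first step (camera, adjusted p = 0.899), with a median log2 fold change of -0.07 and a mean of 0.67, and MEOX1 and TCF15 rose and PAX2 fell at the second (camera, adjusted p = 0.918). The amnion and trophectoderm list at the second step had GATA2 and IGFBP3 higher and KRT7 and TFAP2C lower (camera, adjusted p = 0.918), and 4 of 11 Nodal and activin targets, among them SMAD7, SKIL and GSC, rose while 2, among them CER1, fell (camera, adjusted p = 0.218), with a median log2 fold change of 0 (1.47 with genes at 0 set to their bound) and a mean of 0.24. The endoderm and skeletal muscle lists had 4 tested genes each and were not tested as lists. Of the endoderm genes TTR rose at the first step and SOX17 and PRDM1 at the second; of the muscle genes PAX7 rose and DES, ACTA1 and TNNT1 fell at the first step, and DES rose and PAX7, ACTA1 and TNNT1 fell at the second. Adjusted over the list alone, the counts differed for sterol genes at the first step (13 lower) and in mdEM against iPSCs (0 higher and 7 lower). They also differed for mesoderm at the first step (2 higher) and immediate early genes at the second (3 lower).

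Replicate 2 of the NCC aggregates and replicate 2 of mdEM lay apart from the other libraries of their groups. After thinning every library to the smallest total, the smaller BCV of the groups was 0.201. The BCV leaves out counting error, which is what depth changes, so thinning could not decide whether sequencing depth played a part. In total counts, replicate 2 was the lowest of the NCC aggregates and lay between the other libraries of mdEM. Transcript GC content as the whole cause was argued against, although transcript rather than amplicon GC content was used. The smaller BCV with GC offsets was 0.178, above the 0.119 of the NCC aggregates and 0.0934 of mdEM without replicate 2. A part for GC content stayed open, as the deviation of replicate 2 followed GC content with Spearman's rho of -0.440 in NCC aggregates and 0.252 in mdEM across genes, which are not independent replicates. Replicates 1 and 3 had rho of 0.191 and 0.415 in NCC aggregates and -0.151 and -0.230 in mdEM. Each deviation is taken from the other libraries of the group, so these values are linked. Epithelial cells in mdEM replicate 2 may also contribute and cannot be told apart from other causes, since 57.9% of the epithelial adhesion genes were highest there.

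The iPSC libraries lay closer together, with a BCV of 0.0573, than the aggregate libraries. An unusual library in each aggregate group was argued against as the whole cause, since the smaller BCV without replicate 2 was still 0.0934, and so was GC content, with 0.178 after GC offsets. Adherent against aggregate culture was not tested and goes with the stage.

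The rise of endothelial genes in mdEM may come from endothelial cells. Of the 8 pan-endothelial genes set down for the test, 3, CDH5, KDR and TIE1, were called higher. This lay between the 6 set as the mark for such cells and the 2 set as the mark against them. PECAM1, CLDN5, ERG and ESAM had too few counts to be tested, so 6 could not be reached and the count does not decide the question. TEK fell from 30.0 ± 3.58 to 7.09 ± 3.55 CPM, and PECAM1, ERG and ESAM were at 0.350, 0.580 and 1.02 CPM in mdEM. CLDN5 had 0 counts in NCC aggregates and mdEM, where its amplicon may have failed. FLI1, which rose from 0.406 ± 0.228 to 104 ± 14.6 CPM, is also in the ectomesenchyme list, so endothelial cells and expression by ectomesenchyme itself cannot be told apart.

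Other splits of the libraries were fitted too. For a pair of groups only their 6 libraries were used, so the real counts differ from those of the fit to all 9 libraries. For 2 groups of 3 there are 10 splits, too few for a share under 0.05. In NCC aggregates against iPSCs 1 of 10 splits, the real one, called as many genes (9374; highest other 0) and lists (19; highest other 13). In mdEM against NCC aggregates it was 1 of 10 for genes (4379; 0) and for lists (17; 14), and in mdEM against iPSCs 1 of 10 for genes (10019; 0) and for lists (17; 9). For the difference among the 3 stages, 1 of 100 splits drawn from 280 gave as many genes, the real one, which is always drawn. It called 11175 genes, and the highest other split called 7098. No other drawn split reached the real count, but the replicates may not be separate cultures, so chance differences between cultures were not excluded. For genes higher at day 5 than at both other stages 4 of 100 splits gave as many (994; highest other 2960), and for genes lower at day 5 also 4 of 100 (1055; 3621). In the other splits the group set in the place of day 5 was picked at random, so it could be the iPSC libraries kept together. Such a split would count genes that set iPSCs apart from both aggregate stages. Whether the splits with several times the real count were of this kind was not checked, so these shares are not taken to exclude chance.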
